A study of Mus musculus with 4 samples.

How the data were processed

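Single-cell RNA sequencing of mouse plantaris muscle, a small plantarflexor of the calf that grows when it is overloaded, gave 4 libraries. Per the labels, muscles were broken up mechanically and enzymatically into mononuclear suspensions and made into droplet-based 3' libraries (10x Chromium v3). Per the labels they were Pax7-tdT and Pax7-DTA muscle at 4 days of overload, and Pax7-tdT and tdT parental muscle at 14 days. Each group had 1 library, and per the series design each library pooled muscles of multiple mice. As such lines are built, in the Pax7-tdT genotype a recombinase under the Pax7 gene is used to switch on the red reporter tdTomato in satellite cells, the muscle stem cells. In the Pax7-DTA genotype it is used to switch on a diphtheria toxin fragment that kills them. The parental line carries the reporter with no Pax7 driver in its label. The series design states that a subset of cells was sorted, to follow the reporter transcript out of satellite cells. Which libraries that concerned, and through which gate, was not given in the sources used here.

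The deposited tables hold unique molecular identifier (UMI) counts per gene and cell barcode. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat were used with the mouse build GRCm38; which step each made, and the version of Seurat, were not given in the sources used here. The values in the deposited tables were whole counts and were used as such. Each library also had deposited tables of spliced, unspliced and ambiguous counts, whose counting tool was not given in the sources used here. In the Pax7-tdT 14-day library ribosomal protein genes made up 5.90% of the spliced and 14.4% of the total UMIs of the same barcodes, so that spliced table was not counted on the same basis. The total tables listed 13936 genes at 4 days and 14824 at 14 days, of which 13699 were in all 4 libraries, and the spliced tables listed 21858. Pax7 was missing from the total tables at 4 days, so Pax7 was read from the spliced tables of all 4 libraries, over kept barcodes present in both kinds of table (3853, 2930, 4836 and 6998 in Pax7-tdT 4 d, Pax7-DTA 4 d, Pax7-tdT 14 d and tdT parental 14 d, an order kept throughout). Both reporter genes were read from the total tables, because tdTomato was 0 throughout the spliced ones. The deposited annotation of the reporter sequence has 2 genes. The stop cassette, named tdTomatoStop, spans positions 1467 to 2337 and precedes tdTomato at 2418 to 4736, so the ratio of their UMIs separates the intact from the recombined reporter. Gene positions came from GENCODE M21 on GRCm38. The annotation release used by the submitters was not given in the sources used here.

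Barcodes were kept with at least 500 UMIs, at least 250 genes and at most 20% mitochondrial UMIs. The tables already held no barcode under 750 genes and none over a mitochondrial share of 25%, so only the mitochondrial limit removed any (31, 24, 34 and 36 barcodes). Doublets were scored per library with scrublet in scanpy 1.11.5 at an expected rate of 6%. It marked 0.049%, 0%, 2.14% and 3.61% of barcodes, so at 4 days it removed almost none. After both steps 4082 of 4115, 3515 of 3539, 5118 of 5264 and 7877 of 8208 barcodes were kept. Counts were scaled to 10000 per cell and logged, and 2000 variable genes were chosen with library as batch. The reporter, mitochondrial, ribosomal protein, haemoglobin, Xist and Y-linked genes were left out of clustering. The steps after that were 30 principal components, 20 exact neighbours and Leiden clustering at resolution 0.8 with a fixed seed (igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, Python 3.11.15). No integration across libraries was applied.

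Clusters took their names from 15 lists of cell type markers fixed before the data were examined, as the class whose markers had the highest mean log2 ratio to the median cluster, with at least 3 of them raised more than 1 log2 unit in it. The classes are written with the ending "-like" because no surface protein was measured. A cluster with no marker of its class among its 10 leading genes was named only when that class led the next by at least 1.0 in score, a rule set after the clusters were seen. FAP-like cluster 10 met it, and cluster 12 did not and stayed unnamed. FAP stands for fibro-adipogenic progenitor, the matrix-producing stromal cell of muscle. Myogenic-like cells were clusters 15 and 16, FAP-like cells 8, 9 and 10, macrophage/monocyte-like cells 3, 5, 7 and 13, and each other class was 1 cluster. No cluster was named after lymphatic endothelial, B, mast, glial or erythroid cells. Expression is in CPM, UMIs scaled to the same standard total in every class and library. The summed CPM of each class's markers were computed in every other class as a measure of RNA from other cells.

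With 1 library per group no test between groups was possible, and cells of 1 library are not replicates of a treatment. Values are given per library with exact 95% intervals, Clopper-Pearson for shares and Garwood for counts, and the intervals of ratios are conditional on the summed UMIs. All of these cover counting error only, not the spread between mice, dissections or libraries. Within a class, UMIs were summed over cells and the log2 ratio of CPM was taken with 0.5 UMI added to each sum, for classes with at least 100 cells in both libraries. Where 1 library had no UMI, the fold is a bound computed against 3 counts in that library and class. It takes the count of the other library as exact, so the limit of the ratio's interval lies nearer to no difference. Ratios against 1 to 3 counts are given with their intervals.

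The gene lists, fixed before the data were examined, were chemokines, collagens, matrix glycoproteins and matricellular genes, matrix proteases and inhibitors, proliferation, immediate early and dissociation stress genes, interferon response, inflammatory cytokines, pro-repair macrophage genes, MHC class II presentation, angiogenesis, TGF-beta and BMP signalling, complement, muscle growth factors, satellite cell quiescence and myogenic differentiation. Members with at least 20 UMIs over the compared libraries counted as measured. A list's median log2 ratio is given with its percentile among 10000 random lists of the same size, matched in 20 bins of mean expression, as a description of these libraries. A gene at 0 in 1 library lies beyond the median wherever its bound does, and then does not set it.

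Genes were named by a rule fixed before the data were examined. For each comparison and each of the 3 classes with most cells, it took the 4 genes with the highest and the 4 with the lowest log2 ratio among those with at least 100 CPM and 30 UMIs in the library where the gene was higher. Mitochondrial, ribosomal protein, haemoglobin, predicted, sex-linked and other classes' marker genes were left out, as were genes with under 20% of the CPM they had in another class of that library. Pax7, tdTomato, Ccn4, Mmp9 and the highest, lowest and most abundant member of each list described were named whatever their values. Not every gene that the rule takes is printed. Other genes named in the text were chosen after their values were seen.

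The procedure was tested on simulated data made from the FAP-like counts, with known log2 ratios of 1 and 2 in either direction. The intervals held the true ratio for at least 96.0% of genes in each of the 3 comparisons. The simulated counts held counting error only, as the intervals assume. This checks the computation and not the spread between cells or libraries or the effect of free RNA. Alternatives covered the UMI minimum, a mitochondrial limit of 10%, no doublet removal, Leiden resolutions of 0.4 and 1.5, clustering each library alone, the spliced table, thinning every cell to 1000 UMIs, centring on the median ratio of all genes, 5 added UMIs, no minimum count for list members, and reporter measures. Others were added after the data were seen, and the closing section names them. Total UMIs per table were 39132478, 36529723, 67618107 and 32124348, and median UMIs per kept cell were 6356, 4771, 9856 and 3253. Trajectories and velocity were not analysed here, and raw reads were not used here.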

Results

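Transcripts were counted in single cells of overloaded mouse plantaris muscle in 4 libraries of 1 group each: Pax7-tdT at 4 days (4082 kept cells), Pax7-DTA at 4 days (3515), Pax7-tdT at 14 days (5118) and tdT parental at 14 days (7877). Total UMIs per table were 39132478, 36529723, 67618107 and 32124348, and median UMIs per kept cell were 6356, 4771, 9856 and 3253. There were no replicate libraries, so no difference between groups was tested, and the intervals given cover counting error only. Because a subset of cells was sorted and depth differed, shares of cells describe the suspensions sequenced and not the muscle. The Y-linked genes Ddx3y and Eif2s3y were at 19.3 and 17.1 CPM in Pax7-tdT and 10.9 and 7.98 CPM in Pax7-DTA at 4 days. At 14 days they were at 86.7 and 56.6 CPM in Pax7-tdT and 71.8 and 19.4 CPM in the parental library. Whether the pools of mice differed in sex was not tested.

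Immune cells filled most of the suspensions at 4 days, and stromal and muscle cells filled more of them at 14 days. Macrophage/monocyte-like cells (clusters 3, 5, 7 and 13) were 44.5% (95% interval 43.0 to 46.0) of cells in Pax7-tdT and 45.0% (43.4 to 46.7) in Pax7-DTA at 4 days, against 25.6% (24.4 to 26.8) in Pax7-tdT and 17.0% (16.2 to 17.9) in the parental library at 14 days. Neutrophil-like cells (cluster 2) were 30.6% (29.2 to 32.1) and 16.9% (15.6 to 18.2) at 4 days. At 14 days 3 such cells were found in Pax7-tdT, a share of 0.0586%, and none in the parental library, which allows a share of up to 0.0381%. FAP-like cells (clusters 8, 9 and 10), the matrix-producing stroma, were 4.70% (4.07 to 5.40) of the Pax7-tdT and 20.5% (19.2 to 21.9) of the Pax7-DTA library at 4 days, and 19.3% (18.2 to 20.4) and 42.6% (41.5 to 43.7) of the 14-day libraries. Among barcodes of at least 6000 UMIs the 4-day shares were 8.48% and 18.5%, and at a Leiden resolution of 1.5 they were 4.53% and 8.93%. Tenocyte-like cells (cluster 14), the cells of tendon, were 0.367%, 0.427%, 7.76% and 19.5%, or 0.416% and 2.08% at 4 days with each library clustered alone. Myofibre-like barcodes (cluster 11), led by the contractile genes Acta1 and Ckm, were 3.58%, 2.19%, 19.7% and 1.78%. Endothelial-like cells (cluster 1) were 4.51%, 2.36%, 5.67% and 10.9%, dendritic-like cells (cluster 0) 7.37%, 5.18%, 1.13% and 3.0%, T/NK-like cells (cluster 4) 2.33%, 4.69%, 0.469% and 0.229%, and mural-like cells (cluster 6) 0.931%, 0.683%, 1.15% and 1.96%. The unnamed cluster 12, led by the osteoclast-type genes Acp5 and Atp6v0d2, Mmp9, and the proliferation genes Stmn1 and Top2a, held 0.955%, 2.08%, 1.33% and 0.787% of cells and came apart at a Leiden resolution of 1.5. The direction of the T/NK-like shares at 4 days depended on the clustering: they were 2.25% in Pax7-tdT and 1.76% in Pax7-DTA at Leiden resolutions of 0.4 and 1.5, and 2.25% and 1.71% with each library clustered alone.

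**Figure D1:**
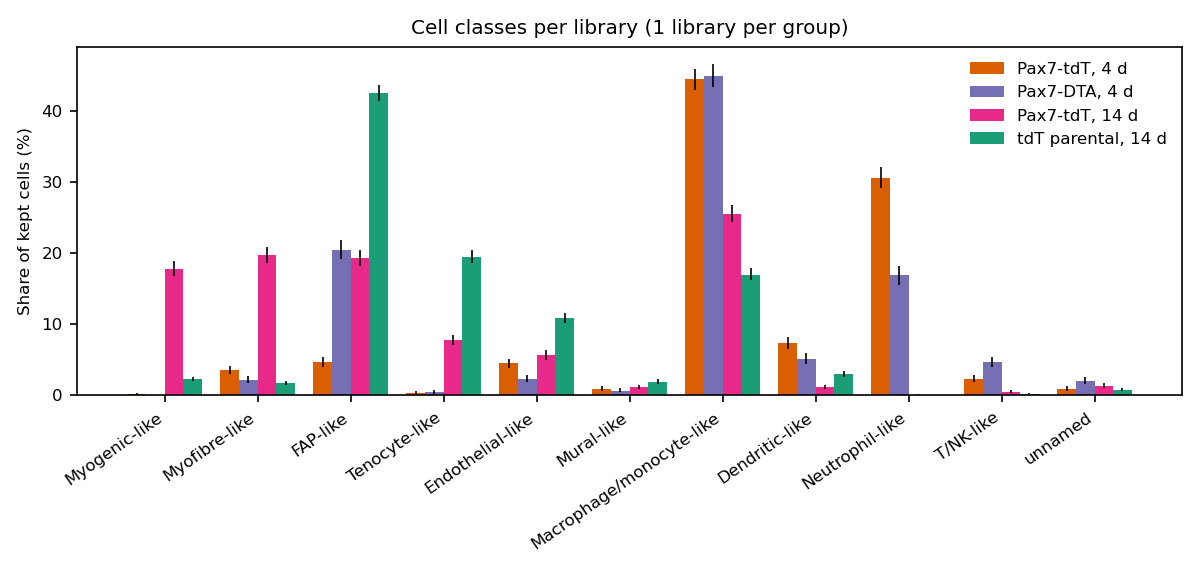
Share of kept cells (%, vertical axis) in each named class for the 4 libraries, with exact binomial 95% intervals as error bars. Neutrophil-like cells stood at 30.6% and 16.9% in the 4-day libraries, and myogenic-like cells reached 17.8% in Pax7-tdT at 14 days.

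Within the macrophage/monocyte-like class, 4-day and 14-day cells lay in different clusters. Cluster 3, led by Arg1, an arginine-degrading enzyme of wound macrophages, and cluster 7, led by the monocyte genes Ly6c2, Chil3 and Plac8, held 1300 and 468 cells of the Pax7-tdT 4-day library and 60 and 14 of its 14-day counterpart. Cluster 13, led by Gdf15, a stress-induced cytokine, and Apoe, a lipid carrier, held 16 and 1164. Cluster 5, led by Ccl12 and the resident macrophage gene Lyve1, held 1170 of the parental cells and 73 of the Pax7-tdT cells at 14 days. FAP-like cells split in a similar way: cluster 10, led by Cxcl5 and Timp1, held 630 of the Pax7-DTA cells and 77 of the Pax7-tdT cells at 4 days, cluster 9, led by Dlk1 and Smoc2, held 789 of the Pax7-tdT cells at 14 days, and cluster 8, led by Sfrp2 and Myoc, held 3194 of the parental cells.

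The first comparison asked whether the satellite cell and reporter genes followed the genotype labels. Pax7, the transcription factor that marks satellite cells (ENSMUSG00000028736, GRCm38 chromosome 4, 139737062 to 139833528, minus strand), had 7 spliced UMIs in Pax7-tdT at 4 days, 1 in Pax7-DTA, 2338 in Pax7-tdT at 14 days and 111 in the parental library. These were 0.227 (0.0911 to 0.467), 0.0341 (0.000864 to 0.19), 52.5 (50.4 to 54.6) and 4.63 (3.81 to 5.57) CPM. Myf5, expressed in satellite cells and myoblasts, had 8, 0, 1077 and 190 spliced UMIs, Myod1, the myoblast determination factor, had 213, 33, 5599 and 127, and Myog, which drives terminal differentiation, had 1184, 4, 9390 and 452. Myogenic-like cells (clusters 15 and 16) numbered 6 in Pax7-tdT at 4 days (0.147%, 0.054 to 0.32) and 0 in Pax7-DTA, which allows a share of up to 0.0853%, so against that floor the share was at least 1.72-fold lower in Pax7-DTA, while the interval of its log2 ratio, which also covers the 6 cells, reached −0.02. Without doublet removal there were 13 and 4 such cells, and at a Leiden resolution of 0.4 there were 15 and 6. The 4-day libraries thus held too few of these cells to describe their expression. At 14 days there were 912 in Pax7-tdT (17.8%, 16.8 to 18.9) and 180 in the parental library (2.29%, 1.97 to 2.64).

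tdTomato was counted in the 3 libraries whose labels name the reporter and not in Pax7-DTA. The gene (reporter sequence positions 2418 to 4736, coding from 2418 to 3845 with an untranslated end at 3849 to 4736) had 1639, 0, 36877 and 2306 UMIs, or 42.0, 0, 568 (562 to 574) and 76.0 (73.0 to 79.2) CPM. tdTomatoStop, the transcript of the cassette that blocks the reporter before recombination (1467 to 2337), had 48333, 501, 88047 and 101519 UMIs, or 1240, 13.7, 1360 and 3350 CPM. In myogenic-like cells tdTomato made up 97.6% (94.5 to 99.2) of the reporter UMIs, meaning both genes together, at 4 days and 97.3% at 14 days in Pax7-tdT, against 2.30% (1.84 to 2.84) in the parental library.

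The second comparison addressed the stated purpose of the sorted cells, whether reporter transcript was found outside satellite cells. At 14 days tdTomato outside the myogenic-like class was 193 (189 to 197) CPM in Pax7-tdT and 74.6 (71.5 to 77.7) CPM in the parental library, a log2 ratio of 1.37. Part of this lay in myofibre-like barcodes, where tdTomato was 17.0% (16.4 to 17.5) of reporter UMIs against 0.524% in the parental library, and part in the unnamed cluster, where it was 86.8% against 2.05%. That cluster held 2629 of the 10396 tdTomato UMIs counted as outside the myogenic-like class in Pax7-tdT. Its 68 cells also held 1202 UMIs of myogenic-specific genes (Pax7, Myf5, Cdh15, Fgfr4 and Myog), against 15331 in the 912 myogenic-like cells. The ratio of 1.37 therefore also covers cells that may be myogenic. In the 13 cells of that cluster without such a UMI the tdTomato share was 9.97%. In the remaining named classes together it was 6.17% (6.01 to 6.35) against 2.41% (2.31 to 2.51), and 104 against 74.1 CPM, a log2 ratio of 0.49. Class by class the Pax7-tdT and parental shares were 6.95% (6.63 to 7.27) and 2.67% (2.48 to 2.87) in FAP-like, 6.36% and 3.82% in tenocyte-like, 6.81% (6.42 to 7.21) and 1.91% (1.73 to 2.10) in endothelial-like, 3.81% (3.56 to 4.08) and 1.44% (1.26 to 1.64) in macrophage/monocyte-like, 17.4% (15.4 to 19.5) and 1.44% in dendritic-like, and 9.11% and 1.47% in mural-like cells. By CPM the classes lay closer, at 83.8 and 54.7 in FAP-like, 83.5 and 78.7 in tenocyte-like, 276 and 177 in endothelial-like, and 74.4 (69.5 to 79.7) and 68.6 (60.0 to 78.1) in macrophage/monocyte-like cells, where a difference was not detectable at this depth. tdTomatoStop in macrophage/monocyte-like cells was 1880 CPM in Pax7-tdT and 4690 CPM in the parental library.

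Outside myofibre-like barcodes most of the Pax7-tdT shares fell once cells that also carried a UMI of a myogenic-specific gene were left out. The macrophage/monocyte-like share fell only from 3.81% to 3.39%. Endothelial-like, macrophage/monocyte-like, dendritic-like and mural-like shares stayed above the parental ones. Without cells that carried such a UMI the myofibre-like share stayed at 15.8% against 0.513%. tdTomato over all cells outside the myogenic-like class was then 96.1 against 74.2 CPM. With the unnamed cluster and the myofibre-like class left out as well, the log2 ratio of tdTomato CPM turned to −0.48 (53.1 against 73.9 CPM), while the share of reporter UMIs stayed higher in Pax7-tdT, at 3.24% against 2.41%. In cells without a myogenic-specific UMI the shares in Pax7-tdT and parental cells were 2.72% and 2.69% in FAP-like, 3.46% and 3.82% in tenocyte-like, 3.59% and 1.90% in endothelial-like, 3.39% (3.15 to 3.64) and 1.44% (1.26 to 1.63) in macrophage/monocyte-like, 4.29% and 1.44% in dendritic-like, and 2.98% and 1.46% in mural-like cells. At 4 days tdTomato outside the myogenic-like class had 1436 UMIs in Pax7-tdT (37.0 CPM) and 0 in Pax7-DTA, at least 449-fold higher against the floor of 3 counts, with a lower limit of 8.51 for the log2 ratio once both counts are given their error. It was 2.89% (2.74 to 3.04) of reporter UMIs there, and by class 2.40% in FAP-like, 2.67% in macrophage/monocyte-like, 2.06% in neutrophil-like, 3.99% in endothelial-like (2.61% without 3 cells that held a myogenic-specific UMI), 6.12% in myofibre-like and 13.5% in mural-like cells, where the 87 tdTomato UMIs lay in 10 of 38 cells and 2 of these held more than 5 UMIs each. The Pax7-DTA label names no tdT reporter, so it gives the background of counting and not of the unrecombined reporter.

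**Figure D2:**
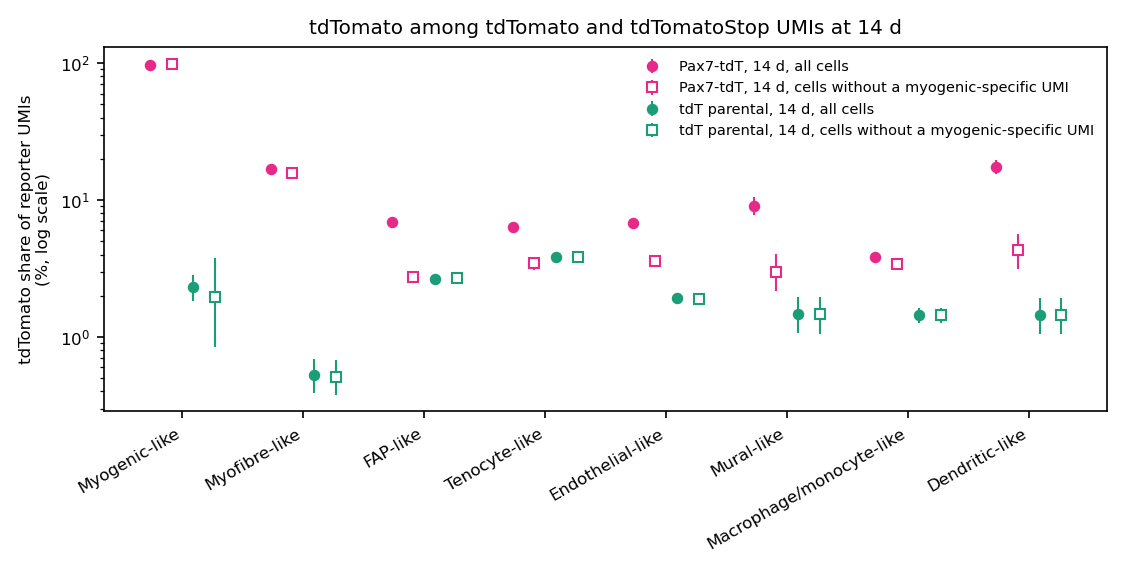
tdTomato as a share of tdTomato and tdTomatoStop UMIs (%, logarithmic vertical axis) per class at 14 days in Pax7-tdT and parental cells. Filled circles are all cells of a class, open squares are cells without a myogenic-specific UMI, and bars are 95% binomial intervals. In FAP-like cells the filled circles lie at 6.95% and 2.67% and the open squares at 2.72% and 2.69%.

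The third comparison set Pax7-DTA against Pax7-tdT at 4 days, the genotype made to lose its satellite cells against the genotype in which they are only marked. In FAP-like cells, chemokine, inflammatory and pro-repair genes were higher in Pax7-DTA and MHC class II genes were lower, while the collagen list as a whole lay near 0. Cluster 10, led by Cxcl5 and Timp1, held 630 of the 721 FAP-like cells in Pax7-DTA and 77 of 192 in Pax7-tdT. Cluster 8, led by Sfrp2 and Myoc, held 63 and 87. The class sums thus compare different mixes of FAP-like clusters, and changes within 1 cluster were not measured. Of 24 measured chemokines 19 were higher, with a median log2 ratio of 0.61 (percentile 100 of the random lists). The monocyte attractant Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453, plus strand) was 2262 against 1242 CPM and the neutrophil attractant Cxcl5 (ENSMUSG00000029371, chromosome 5, 90759360 to 90761624, plus strand) 604 against 114 CPM. The log2 ratio was 2.79 (1.90 to 4.02) for Ccl12, another monocyte attractant, and 0.33 (0.30 to 0.36) for Cxcl1, the most abundant member. The eosinophil attractants Ccl24 and Ccl11 were lower, at −3.07 (−4.94 to −1.70) and −1.08.

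Inflammatory cytokine genes had 15 of 19 members higher in these FAP-like cells (median 0.60, percentile 100). Csf2, a growth factor for granulocytes and macrophages, had 123 UMIs against 0, at least 17.3-fold higher, Tslp was at −0.86 and the inhibitor Nfkbia at 0.07. The pro-repair list had 12 of 16 members higher (median 0.84, percentile 100), led by Spp1, or osteopontin, at 2.57, with the efferocytosis receptor Mertk at −1.24. Complement had 8 of 15 members higher (median 0.15, percentile 99.8), with the alternative pathway factor Cfb at 2.56 and the complement inhibitor Cd55 at −2.20. All 6 measured MHC class II genes were lower (median −0.56, percentile 0.8), from Cd74 at −0.70 to H2-Ab1 at −0.38. Dendritic-like cells, with Cd74 at 32290 CPM in Pax7-tdT, were 7.37% of that library and 5.18% of Pax7-DTA. In neutrophil-like cells Cd74 was at −0.56 too, with H2-Eb1 at 0.14. For MHC class II, a change in free immune RNA was not separated from a change within FAP-like cells. Macrophage markers summed to 2533 CPM in the FAP-like cells of Pax7-DTA and 678 CPM in those of Pax7-tdT. The summed markers include Spp1, at 1210 CPM in FAP-like barcodes of Pax7-DTA under 6000 UMIs and 1460 CPM in deeper ones. Much of the Pax7-DTA sum is thus Spp1, so the sum is not a measure of macrophage RNA separate from the pro-repair list. FAP-like cells had a median of 3078 UMIs in Pax7-DTA and 28385 in Pax7-tdT. With chemokines that were more abundant in macrophage/monocyte-like cells left out the median was 0.33, and with every cell thinned to equal depth it was 1.45. Thinning gives each barcode the same weight. The 430 FAP-like barcodes of Pax7-DTA under 6000 UMIs, with Lyz2 at 1890 CPM against 131 CPM in deeper ones, thus weigh more in the last value.

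The matrix lists of FAP-like cells moved in both directions. Collagens had 9 of 18 members higher (median 0.01, percentile 45.9): Col1a1 was at 0.66 (0.64 to 0.68), the most abundant Col3a1 at −0.11 and Col14a1 at −0.89. Matrix glycoproteins had 12 of 29 higher (median −0.08, percentile 13.5), with the matricellular factor Ccn4 at 118 against 62.4 CPM (log2 0.92), Sparc at 0.07 and Tnxb at −1.89. Proteases and their inhibitors had 12 of 21 higher (median 0.04), with the metalloprotease inhibitor Timp1 at 0.85. The other medians were −0.06 for proliferation (9 of 20 higher), 0.06 for immediate early genes (11 of 20), −0.22 for interferon response (6 of 18), −0.17 for angiogenesis (8 of 18), −0.13 for TGF-beta and BMP signalling (8 of 25, from Id1 at 1.85 to Inhbb at −1.57), −0.17 for muscle growth factors (9 of 20, from Rspo3 at 2.47 to Fgf18 at −1.93), −0.19 for satellite cell quiescence (3 of 10) and 0.40 for myogenic differentiation (8 of 11). The median of all genes in the class was −0.15, and after centring on it the glycoprotein, proliferation and TGF-beta medians turned positive. Among all genes, Saa3, an acute phase protein, stood at 1.64, and Apod, Myoc and Gsn, genes of resting fibroblasts, at −3.41, −3.05 and −2.07. Wdr89 (3.49) and Nme2 (3.16) are left undescribed, since sharing of reads between similar or overlapping gene copies was not tested.

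Macrophage/monocyte-like cells of Pax7-DTA had 18 of 23 chemokines higher (median 0.38, percentile 100, or 0.23 without members more abundant in FAP-like cells), with the most abundant, Cxcl2, at 0.18 and Cxcl3 at −0.46. Inflammatory cytokines had 14 of 18 higher (median 0.54), with the granulocyte growth factor Csf3 at 2.53, Il1b at 0.39 and the nitric oxide synthase Nos2 at −0.88. Proliferation genes had 15 of 20 higher (median 0.52, Cdk1 at 1.11), and the interferon-induced Ifi44 stood at 3.27 in a list with a median of 0.18. All 9 MHC class II genes were lower (median −0.57, percentile 0.01), from their master regulator Ciita at −1.71 to H2-DMb2 at −0.00, with the most abundant, Cd74, at −0.42. Retnla, a gene of alternatively activated macrophages, had 0 UMIs against 79, at least 19.3-fold lower, within a pro-repair list of median 0.08. Those 79 UMIs lay among 1816 cells of Pax7-tdT, while its 301 dendritic-like cells held 277, or 67.8 CPM. Free RNA of dendritic-like cells was not separated from macrophage expression of Retnla. Ero1l and Bnip3, both induced by low oxygen, were at −1.42 and −1.10, the elastase Mmp12 at −1.24 and AA467197 at −1.31. All 17 measured collagens were higher (median 2.68) beside FAP markers that summed to 674 against 327 CPM in these cells. Ftl1-ps1, Rnaset2a and Wdr89, also among the highest, are left undescribed because sharing of reads was not tested for them either.

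In neutrophil-like cells, the granule genes Camp and Ngp, made by immature neutrophils, stood at −6.16 (5 against 981 UMIs) and −4.96 in Pax7-DTA. The inflammasome adaptor Pycard was at −2.27, and Gdpd3 stood at 4.22, Cox17 at 1.57 and Il1rn, the interleukin-1 receptor antagonist, at 1.49. Nos2 had 1 UMI against 102, a log2 ratio of −4.77 (−10.67 to −2.84). The gelatinase Mmp9 was 1030 against 1290 CPM. Chemokines had 12 of 17 members higher (median 0.24), with Ccl5 at 2.72, the most abundant, Cxcl2, at −0.03 and Ccl2 at −1.46. Collagens had 10 of 11 members higher (median 2.09), beside the FAP genes Postn at 57.5 against 12.6 CPM and Dcn at 36.1 against 15.1 CPM. FAP markers summed to 881 against 936 CPM in these cells. Among them Col1a1 was at 116 against 23.0 CPM and Col3a1 at 138 against 35.6 CPM, while Cxcl14 was at 4.51 against 6.09 CPM. The sum therefore does not show that FAP RNA was alike in the neutrophil-like cells of both libraries. In dendritic-like cells Ccl17, a T cell attractant of mature dendritic cells, had 46 UMIs against 0, at least 29.4-fold higher (limit of the log2 interval 4.52), and Retnla 0 against 277, at least 48.2-fold lower (limit −5.28). The median of all genes was −0.07 in macrophage/monocyte-like, −0.59 in neutrophil-like and −0.11 in dendritic-like cells.

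**Figure D3:**
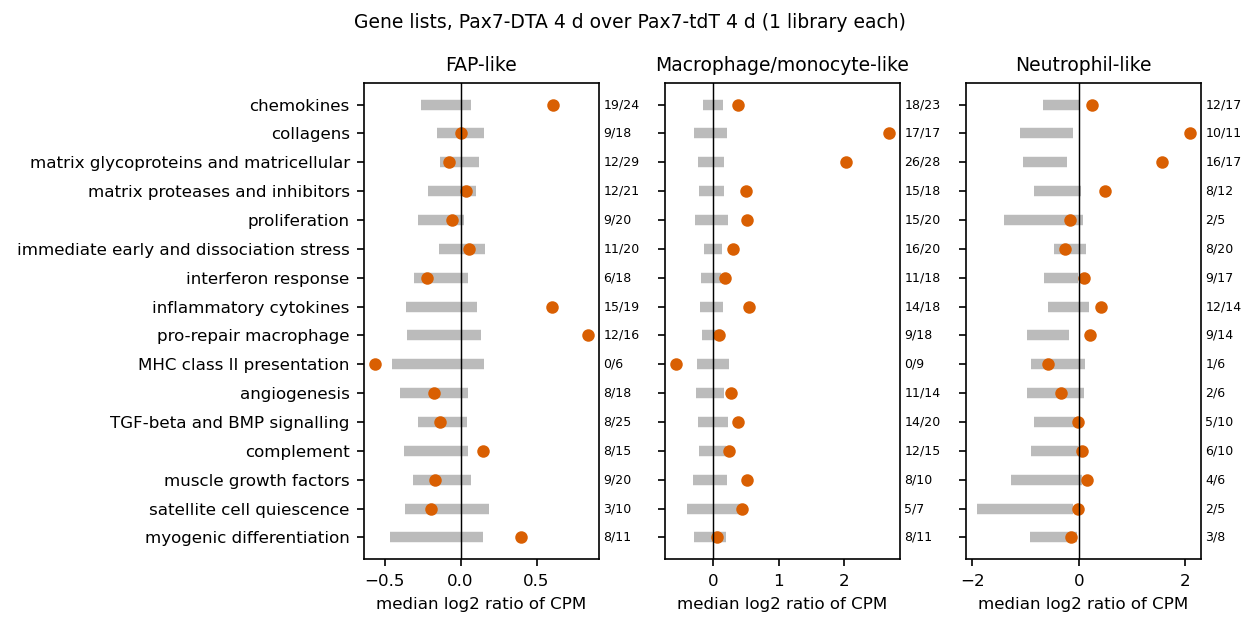
Median log2 ratio of CPM of each gene list, Pax7-DTA over Pax7-tdT at 4 days (horizontal axis), in FAP-like, macrophage/monocyte-like and neutrophil-like cells. Orange points are list medians, grey bars span 95% of 10000 random lists matched on mean expression, and the numbers at the right are members higher and members measured. The chemokine median lies at 0.61 in FAP-like cells and MHC class II at −0.57 in macrophage/monocyte-like cells.

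The fourth comparison set Pax7-tdT muscle at 14 days against 4 days. Each day was 1 pool of mice, and Ddx3y was at 86.7 against 19.3 CPM, so time and the mice pooled cannot be told apart. FAP-like cells at 14 days had lower proliferation, interferon and MHC class II genes and higher collagen and matrix glycoprotein genes than at 4 days. All 20 proliferation genes were lower (median −2.74, percentile 0), with thymidine kinase Tk1 at −4.45, Top2a, a DNA topoisomerase, at −3.16 and Pcna, the replication clamp, at −0.37. The named genes Pclaf and H1f5 belong to the same process and stood at −3.42 and −4.04. With each library clustered alone the list median was −6.03. There a 14-day cluster of 86 cells led by Ube2c and Top2a stayed unnamed, outside the class. Cluster 10, whose leading genes include H1f5, Birc5 and Pclaf, held 77 of the 192 FAP-like cells at 4 days and 22 of 986 at 14 days. Cluster 9, led by Dlk1, held 28 and 789. The class sums thus compare different mixes of FAP-like clusters, and changes within 1 cluster were not measured. Of 18 collagens 17 were higher (median 1.06), with the fibril collagen Col11a1 at 1.79, Col3a1 at 0.99 and Col5a3 at −0.63. Of 29 matrix glycoproteins 20 were higher (median 0.68): elastin, Eln, stood at 3.49, Sparc at 0.18 and the collagen cross-linker Loxl2 at −1.09. Matrix proteases and inhibitors had 18 of 22 higher (median 0.72), with the gelatinase Mmp2 at 1.65, Timp1 at −1.47 and Mmp9 at −5.15 (4 against 46 UMIs). Interferon response had 1 of 18 higher (median −1.35), from Rsad2, an antiviral enzyme, at −2.86 to Irf1 at 1.04, and all 6 MHC class II genes were lower (median −2.11). Neutrophil-like cells went from 30.6% to 0.0586% and dendritic-like cells from 7.37% to 1.13% of these libraries. At 4 days Mmp9 stood at 1290 CPM in the former and Cd74 at 32290 CPM in the latter. For Mmp9 and MHC class II, loss of free immune RNA was not separated from a change within FAP-like cells.

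Immediate early genes, which tissue dissociation also induces, were higher in all 20 members at 14 days (median 1.11), from Fos at 0.44 to Atf3 at 1.77. Chemokines (12 of 24 higher, median 0.05) and inflammatory cytokines (8 of 15, with Il6 at 2.14 and Il1b at −5.08) showed no common direction in FAP-like cells. Il1b stood at 11260 CPM in neutrophil-like cells of Pax7-tdT at 4 days, and loss of their free RNA was not tested as a source of its fall. Cxcl13, a B cell attractant (ENSMUSG00000023078, chromosome 5, 95956951 to 95961068, plus strand), had 0 UMIs against 84, at least 96.2-fold lower, and the growth factor Igf2 had 50 against 0, at least 4.85-fold higher. The parental library had 110 Cxcl13 UMIs in FAP-like cells at the same 14 days, so the count of 0 cannot be ascribed to time. TGF-beta and BMP signalling had 20 of 25 higher (median 0.45), with the matrix-bound regulator Ltbp4 at 2.53 and activin A, Inhba, at −1.90. The genes furthest up included Dlk1, a Notch-family ligand of progenitors (ENSMUSG00000040856, chromosome 12, 109452823 to 109463336, plus strand), at 4.55, the cell cycle inhibitor Cdkn1c at 3.60 and the growth factor Mdk at 3.31. Quiescence genes had 9 of 10 higher (median 1.41) and myogenic differentiation 12 of 13 (median 1.77, Acta1 at 3.64), beside 175 Myod1 UMIs against 0 and muscle fibre markers that summed to 1100 CPM in these cells at 14 days and 102 CPM at 4 days.

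In macrophage/monocyte-like cells interferon response genes were lower and pro-repair and complement genes mostly higher at 14 days. Cluster 3, led by Arg1, held 1300 of these cells at 4 days and 60 at 14 days. Cluster 13, led by Gdf15, held 16 and 1164, so these class sums too compare different mixes of clusters. The genes furthest down were Arg1, Plac8, Chil3 and Ly6c2. Arg1 (ENSMUSG00000019987, chromosome 10, 24915221 to 24927484, minus strand) had 21 UMIs against 32836, a log2 ratio of −9.81, Plac8 was at −6.25, the chitinase-like Chil3 at −5.97 and the monocyte antigen Ly6c2 at −5.82. The adhesion molecule Vcam1 was at 4.22, the growth factor Hbegf at 3.70, the iron transporter Slc11a2 at 3.38 and Gdf15 at 3.35. Interferon response had 1 of 18 higher (median −1.48, Ifit2 at −2.86). Pro-repair genes had 12 of 18 higher (median 1.09), with Retnla at 4.38 and Spp1 at −2.64. Complement had 12 of 15 higher (C4b at 2.41), chemokines 16 of 21 (median 0.49, Cxcl9 at 3.58, Cxcl5 at −4.29) and MHC class II 6 of 9 (median 0.65, Cd74 at 1.05). Collagens (17 of 17 higher, median 2.48) and myogenic differentiation genes (14 of 15, median 3.36, creatine kinase Ckm at 5.38) were higher beside fibre markers that summed to 7374 CPM at 14 days and 334 CPM at 4 days.

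Endothelial-like cells had all 20 immediate early genes higher at 14 days (median 1.62, Socs3 at 2.56), 1 of 20 proliferation genes higher (median −1.37, Top2a at −2.23, Pcna at 0.67), 15 of 17 collagens higher (median 1.44) and all 6 MHC class II genes lower (median −2.63). The angiogenesis list lay near 0 (8 of 20 higher, median −0.05), with the VEGF receptor Flt1 at −0.09. Chemokines had 8 of 19 higher (median −0.96). Csf3, the phosphatase Dusp2, the interferon-induced chemokine Cxcl10 and Rnd1 stood at 3.33, 3.38, 3.09 and 2.97, and the arterial connexin Gja4 and mitotic kinesin Cenpe at −2.60 and −2.44. Arg1 had 0 UMIs against 302 in these cells, at least 185-fold lower, beside macrophage markers that summed to 632 against 1740 CPM and neutrophil markers to 11.9 against 1259 CPM. Sap18 is left undescribed because sharing of reads was not tested. Myofibre-like barcodes had 1 of 8 inflammatory genes higher (median −2.61), beside neutrophil markers that summed to 1.78 against 1823 CPM, and the slow fibre troponin Tnnt1 at 1.71. The median of all genes was −0.13 in FAP-like, −0.14 in macrophage/monocyte-like, −0.07 in endothelial-like and −0.19 in myofibre-like cells.

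**Figure D4:**
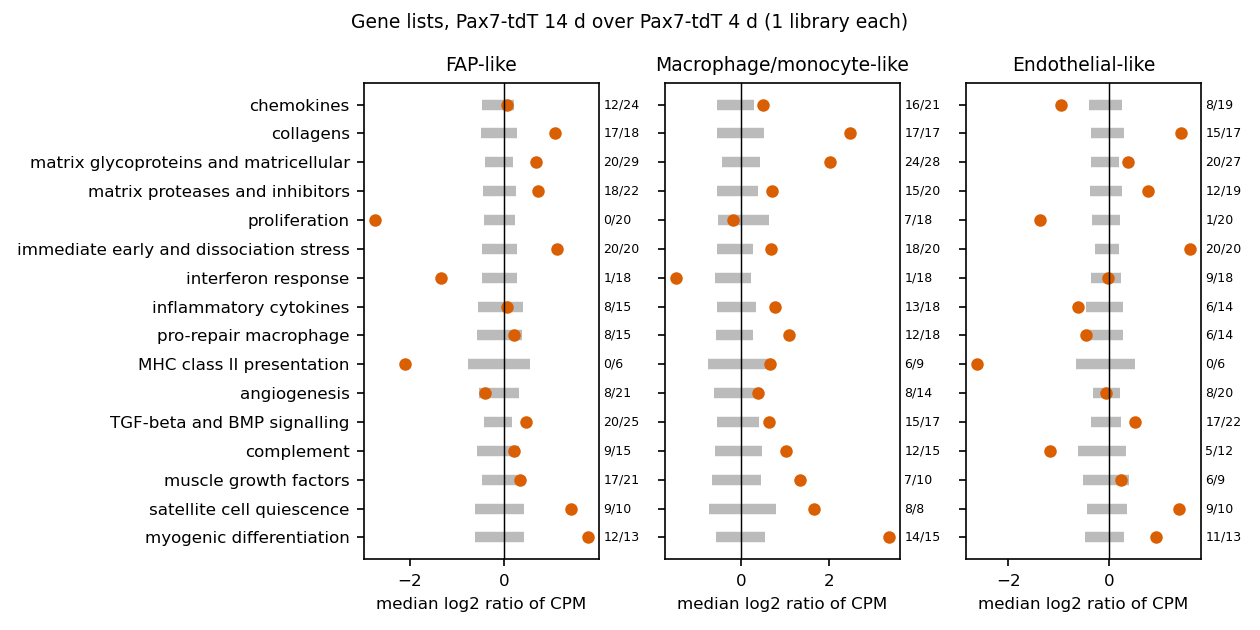
Median log2 ratio of CPM of each gene list, Pax7-tdT at 14 days over 4 days (horizontal axis), in FAP-like, macrophage/monocyte-like and endothelial-like cells. Orange points are list medians, grey bars span 95% of 10000 random lists matched on mean expression, and the numbers at the right are members higher and members measured. Proliferation lies at −2.74 in FAP-like and −1.37 in endothelial-like cells, and collagens at 1.06, 2.48 and 1.44 in the 3 classes.

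The fifth comparison set Pax7-tdT against parental muscle at 14 days, which per the labels differ in genotype. Cluster 9, led by Dlk1 and Smoc2, held 789 of the 986 FAP-like cells of Pax7-tdT. Cluster 8, led by Sfrp2 and Myoc, held 3194 of the 3356 parental ones. Of macrophage/monocyte-like cells, cluster 13 held 1164 of 1311 in Pax7-tdT and cluster 5 held 1170 of 1340 in the parental library. The class sums thus compare different mixes of clusters, and changes within 1 cluster were not measured. FAP-like collagens lay near 0 as a list (9 of 18 higher, median 0.01, Col18a1 at 0.88, Col1a2 at −0.75), while complement was lower in 13 of 15 members (median −1.01, percentile 0), with C4b at −2.30 and the C1 inhibitor Serping1 at −0.65. The regulators Rgcc, Dlk1 and Pxdc1 stood at 2.36, 2.31 and 2.03 and the Wnt modulator Sfrp2 at −2.52. Immediate early genes had 13 of 20 higher (median 0.41), chemokines 12 of 24 (median −0.02), and quiescence genes 9 of 13 (median 0.95, Pax7 at 3.84 from 96 against 4 UMIs), beside 298 against 19 UMIs of the myogenic-specific genes in these cells and Myod1 at 8.59 against 0.955 CPM. Cxcl13 had 0 UMIs in Pax7-tdT against 110 in parental FAP-like cells, at least 54.9-fold lower, and 0 against 495 in macrophage/monocyte-like cells, at least 554-fold lower. It also had 0 against 52 in endothelial-like and 0 against 25 in myofibre-like cells, so its absence was not particular to 1 class of this library. In macrophage/monocyte-like cells, Mmp19, a matrix protease, Oasl1, an interferon-induced gene, and Ankrd33b stood at 3.37, 3.44 and 3.26, inflammatory cytokines had 15 of 16 higher (median 0.63, Cd14 at 1.62), MHC class II 7 of 8 (median 0.70), and collagens 1 of 18 (median −1.23) beside FAP markers at 495 against 1130 CPM.

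Tenocyte-like cells of Pax7-tdT had 18 of 20 immediate early genes higher (median 0.67), 17 of 18 interferon genes (median 0.75), 12 of 15 inflammatory genes (median 0.91) and 6 of 18 collagens (median −0.41). Socs3, a cytokine signalling inhibitor, Angptl7 and the substance P precursor Tac1 stood at 2.80, 2.85 and 2.68, and the collagenase Mmp13 at −2.65. Myogenic-like cells had 18 of 23 TGF-beta and BMP genes higher (median 0.83, the signal transducer Smad3 at 2.27) and the fusion gene Mymx, which myocytes need to fuse, at 531 UMIs against 0, at least 8.33-fold higher. MHC class II genes were lower in all 5 measured members in these cells (median −3.88), beside macrophage markers that summed to 2147 against 734 CPM and the myeloid gene Lyz2 at 69.2 against 168 CPM, and in all 6 in endothelial-like cells (median −4.05), where macrophage markers summed to 632 against 2288 CPM. Parental cells carried haemoglobin and other erythroid UMIs, at 524 CPM in FAP-like, 522 in tenocyte-like, 1516 in endothelial-like and 1214 in macrophage/monocyte-like cells, against 0.786, 0.343, 0.518 and 1.61 CPM in Pax7-tdT. Lars2, Nme2, Wdr89, Sap18, Rnaset2a and Eif3j1 were among the most different genes and are left undescribed because sharing of reads was not tested. The median of all genes was 0.18 in myogenic-like and −0.30 in myofibre-like cells.

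Unspliced UMIs made up 15.5%, 14.8%, 18.3% and 12.5% of the UMIs of the 4 libraries. Ribosomal protein genes held 5.90% of spliced UMIs but 14.4% of total UMIs in Pax7-tdT at 14 days, against 14.7% and 15.3% in Pax7-tdT and 17.2% and 17.3% in Pax7-DTA at 4 days and 13.1% of spliced UMIs in the parental library, so unspliced shares and spliced CPM are not on the same basis in that library. Without those genes the unspliced shares were 17.3%, 17.0%, 19.1% and 13.8%. With them, the share in myofibre-like barcodes was 3.03%, 3.09%, 2.47% and 4.68%, and in myogenic-like cells it was 24.1% in Pax7-tdT and 15.1% in the parental library at 14 days.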

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

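All tests weighed here were chosen after the results were seen, and the test on myogenic RNA is a later version: the first, which compared cells without a myogenic-specific UMI, was dropped because such cells can still hold myogenic RNA. It had given tdTomato shares of reporter UMIs of 2.95% in Pax7-tdT and 3.13% in parental FAP-like and tenocyte-like cells at 14 days, and of 3.46% and 1.70% in macrophage/monocyte-like and endothelial-like cells. A version with the parental level taken only as the ratio to tdTomatoStop was then widened to CPM. The test on the unrecombined cassette was also replaced, because its first version took only cells with a myogenic-specific UMI, a choice that fixed the outcome. A test on the endothelial-like share was added, and the tests on shares and on the cassette were repeated under 6 clusterings, the reported one included.

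A signal appeared where the label names no reporter. The Pax7-DTA library at 4 days had 501 tdTomatoStop UMIs in 309 cells, above the limit that a count of 0 allows, and no tdTomato UMI. Molecules swapped in from the Pax7-tdT 4-day library would have brought 17.0 tdTomato UMIs at that library's ratio of the reporter genes, against 0 observed and a floor of 3 counts. At the ratios of the Pax7-tdT and parental 14-day libraries swaps would have brought 210 and 11.4, so the tables argue against a swap from any of the 3 other libraries alone. Whether this genotype carries the intact cassette was not given in the sources used here.

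The 14-day Pax7-tdT library had more tdTomato outside myogenic-like cells than its parental counterpart. Transcription through the unrecombined cassette at the parental level alone should leave no more tdTomato than that level brings class by class, but named classes other than myogenic-like and myofibre-like held 1.41 times (1.34 to 1.49) that number by CPM and 2.82 times (2.67 to 2.97) by the ratio to tdTomatoStop (1.17 and 2.36 with each library clustered alone), while cells without a myogenic-specific UMI held 0.732 and 1.43 times, so there it cannot be told. Myogenic RNA in the same droplet, from doublets or free RNA, would bring, of the tdTomato above the parental ratio to tdTomatoStop, 108.0% in FAP-like and tenocyte-like, 74.4% in endothelial-like and 34.3% in macrophage/monocyte-like cells by the UMIs of Pax7, Myf5, Cdh15 and Fgfr4, and 49.5%, 46.3% and 24.9% once Myog is counted, while fibre RNA would bring 27.1% in macrophage/monocyte-like cells. Of the smaller excess above the parental CPM, myogenic RNA would bring 256%, 152% and 275%, or 117%, 94.6% and 199% with Myog, and fibre RNA 217% in macrophage/monocyte-like cells. In these classes RNA of other cells and transfer of the transcript cannot be told apart, because the result turns on the genes counted and on how the parental level is scaled.

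The FAP-like share at 4 days was 4.36 times higher (3.71 to 5.14) in Pax7-DTA than in Pax7-tdT. Among barcodes of at least 6000 UMIs it was 18.5% against 8.48%, a ratio of 2.18 (1.80 to 2.64), and at least 2.09 in each of 6 clusterings, so shallow barcodes that hold free RNA do not account for all of it. The 430 FAP-like barcodes of Pax7-DTA under 6000 UMIs had 113 CPM of the FAP receptor gene Pdgfra, 15300 CPM of Col1a1 and 1890 CPM of the myeloid gene Lyz2, against 121, 10300 and 131 CPM in the 291 deeper ones. A suspension with more stromal cells of every kind would also hold more endothelial-like cells, but their share was 0.524 times (0.399 to 0.682) as high and 0.518 times with each library clustered alone, while the summed share of endothelial-like, mural-like and tenocyte-like cells was 0.598 times (0.477 to 0.747) as high but 0.88 times (0.718 to 1.08) clustered alone, so a suspension with more stromal cells as a sum cannot be told. Loss of satellite cells, the sort and the dissection of 1 pool of mice per group stay open as untested explanations.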

How the results depend on the processing

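Most alternatives were fixed before the data were examined, while the fixed doublet score, the 6000-UMI limits, the alternatives for the FAP-like and T/NK-like shares, the choices of list members by class, the choices of cells outside the myogenic-like class and the reporter share were added after seeing the data. No paired analysis was possible because each group had 1 library. A minimum of 1000 UMIs removed no barcode and so tested nothing, the spliced table gave no value for tdTomato, and with each library clustered alone no myogenic-like cluster was found in Pax7-tdT at 4 days, so the myogenic-like share had no value.

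Values are log2 ratios. tdTomato outside myogenic-like cells at 14 days (1.37) reversed to −0.48 without the unnamed cluster, the myofibre-like class and cells with a myogenic-specific UMI. It was 0.99 without the unnamed cluster, 0.49 without the myofibre-like class as well, 1.11 thinned, 2.36 and 1.14 by cells with at least 2 and 1 UMIs, and 2.26 by reporter share, or 0.42 by that share in the restricted cells. The 4-day bound (8.81) was 5.60 thinned and 6.31 and 7.96 by cells with at least 2 and 1 UMIs, since the floor scales with the total. The FAP-like chemokine median (0.61) was 0.51 at Leiden 1.5, 0.45 with each library clustered alone, 1.45 thinned, 0.76 centred, 0.51 in FAP-like barcodes of at least 6000 UMIs and 0.33 without members more abundant in macrophage/monocyte-like cells. The macrophage/monocyte-like chemokine median (0.38) was 0.45 centred, 0.48 with no minimum count and 0.23 without members more abundant in FAP-like cells. The FAP-like collagen median (0.01), which has no clear direction, was 0.041 at a mitochondrial limit of 10%, 0.054 at Leiden 0.4, 0.091 clustered alone, −0.36 thinned and 0.15 centred. The FAP-like proliferation median (−2.74) was −2.63 at the 10% limit, −2.95 without doublet removal, −6.03 clustered alone and −2.61 centred. The FAP-like share ratio (2.12) was 1.12 among barcodes of at least 6000 UMIs, 0.98 at Leiden 1.5, where a shallow cluster lost the name, and 1.78 clustered alone. The T/NK-like share ratio (1.01) reversed to −0.36 at the 10% limit, −0.35 at Leiden 0.4 and at 1.5, and −0.40 clustered alone, so its direction is not supported. The cause was not tested except where centring, the floor or the cells left out fix it by construction. The myogenic-like share ratio (−0.78, a bound against 0 cells) kept its direction but not its counts: it was −1.48 from 4 and 13 cells without doublet removal and −1.11 from 6 and 15 at Leiden 0.4, and the other values stayed within their counting intervals. The 4-day myogenic values rest on 6 cells and 7 Pax7 UMIs in Pax7-tdT.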

Other observations

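The unnamed cluster 12 was not part of any comparison. It held 39, 73, 68 and 62 cells of the 4 libraries and was led by genes of osteoclasts, Acp5 and Atp6v0d2, with Mmp9 and the cell cycle genes Stmn1 and Top2a. It was a mixture: at a Leiden resolution of 1.5 a cluster led by Stmn1 and Top2a took 25, 40, 68 and 61 of these cells, and one led by Acp5 and Mmp9 took 13, 33, 0 and 0. Its tdTomato level in Pax7-tdT at 14 days was 1730 CPM, against 2380 CPM in myogenic-like cells. The cluster held 1202 myogenic-specific UMIs in that library, and its 13 cells without any had 152 CPM of tdTomato. Among macrophage/monocyte-like cells the gelatinase gene Mmp9 was at 39.6 CPM in Pax7-tdT and 29.7 CPM in Pax7-DTA at 4 days, and at 2.95 CPM in Pax7-tdT at 14 days. It was at 1290 CPM in neutrophil-like cells of Pax7-tdT at 4 days, and free RNA from those was not separated from macrophage expression. Ccn4, a matricellular gene, was at 186 CPM in tenocyte-like, 121 CPM in FAP-like and 81.4 CPM in myogenic-like cells of Pax7-tdT at 14 days, and at 154, 68.8 and 47.8 CPM in those of the parental library.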
